A study of Mus musculus with 16 samples.

How the data were processed

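RNA of GFP-sorted mouse leukaemia cells was sequenced in 16 libraries of 5 groups. Per the labels' protocols, libraries were made with the NEBNext Ultra II RNA kit after oligo-dT enrichment of RNA isolated with TRIzol. Whether the libraries or the counting kept strand is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. The deposited table holds expected counts, that is estimated counts per gene that need not be whole, for 55487 genes in 16 columns. The submitters' processing notes name Trim Galore, FastQC, MultiQC, STAR and RSEM without versions or roles, and the genome build GRCm38. The authors also deposited a TPM file per library. TPM values entered only the check of which column belongs to which library, where each of 16 files correlated best with its own column across genes (lowest r = 0.939), and no test. Between 5.81 and 10.9% of the values in a library's expected counts were not whole. Of the gene identifiers, 55394 matched GENCODE M21 (GRCm38), and 54586 of these carried the same symbol there. Coordinates are from that annotation, 1-based. 

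Columns were given to libraries by the names in the labels, and 0 columns were left without a library. Groups and replicate numbers were taken from the sample titles. The titles number the replicates without saying that each is a separate animal, so p-values measure the spread between these samples. No pair of replicates was within sampling noise: the lowest chi-square per degree of freedom between replicates was 9.91. Total expected counts ran from 12.26 to 39.42 M (mega-counts) per library. A share or level near 0 is limited by counting error, and 3 counts were taken as the floor of a library.

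Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3; glmQLFit with robust estimation, glmQLFTest) after filterByExpr and TMM scaling. The filter left 14435 genes. All 16 libraries entered 1 model with a mean per group and no other term. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison. A gene was called at an adjusted p under 0.05. Errors of log2 fold changes are approximate standard errors: the absolute log2 fold change over the square root of the F statistic of its test. CPM values are TMM-scaled and given as mean ± SD over libraries.

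Before the data were examined, the 7 comparisons, the tests, 29 gene lists, the alternatives and a rule for naming genes were fixed. The rule took up to 8 genes per direction with the largest log2 fold change among called genes with an average log2 CPM of at least 3 and no overlap between the CPM of both groups, leaving out predicted genes, pseudogenes, antigen receptor segments and small RNAs. Where fewer than 4 passed in a direction, those with the smallest p were named as not passed. The rule added 16 anchor genes in every comparison, up to 4 members of each list with the smallest p, and the most abundant members of lists of other cell types. The few other genes named are said to have been chosen after their values were seen. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 29 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Among 203 list results, 90 were called, and in 1 of these the median, the mean and the test differed in sign. Of the 113 not called, 33 had such a difference.

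Alternatives were DESeq2 size factors, no filter, a mean count of at least 50, the replicate number as a block, only the groups compared, each library left out in turn, the Wald test of DESeq2 1.42.0, limma-voom and a test against a 1.2-fold change. One more, leaving out secondary disease replicate 4 from the comparisons that do not involve it, was chosen after the data were seen. Overlaps between comparisons were set against n1 × n2 / N per direction. Where both comparisons used the same controls, 50 simulated pairs of unchanged groups were set against those controls.

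The steps were tested on simulated counts in which 200 genes were changed by known folds. At a 2-fold change, 47% of changed genes were recovered for bone marrow doxycycline against control, 52% for spleen doxycycline against control and 7% for the difference between the tissues. At a 4-fold change the shares were 86%, 97% and 64% in the same order, over 14174, 14173 and 14190 genes tested. The changed genes had an average log2 CPM of at least 3, and each gene had the same spread in all groups. The real spleen doxycycline libraries were more spread, with a chi-square per degree of freedom between replicates of 313.5 to 681.9. The other 7-day groups had 9.91 to 68.9, so the shares for comparisons with spleen doxycycline may be too high. The tissue comparisons recovered 35% (controls, 14177 genes tested) and 38% (doxycycline, 14173 genes tested) of 2-fold changes and 90% of 4-fold changes in both. Secondary disease against spleen control recovered 52% and 88% over 14184 genes tested, and against spleen doxycycline 51% and 89% over 14162. Pairs with secondary disease replicate 4 had a chi-square per degree of freedom of 312.6 to 342, against 13.19 to 42.57 among replicates 1 to 3. The shares for secondary disease may thus be too high as well. In every comparison the changed list was called, and 0 of the 28 other lists were called by camera. The simulated genes varied independently of one another, so this check cannot show how camera behaves on lists whose genes move together.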

Results

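The transcriptome of mouse leukaemia cells carrying the fusion gene CBFB::MYH11 and GFP was measured by RNA sequencing. Per the design text, the cells held a doxycycline-inducible shRNA against MYH11 and were transplanted into congenic mice. After engraftment, mice drank water with doxycycline (3 mg/ml in 5% sucrose) or sucrose water for 7 days, and GFP-positive cells were sorted from bone marrow or spleen. The labels of the control libraries name only cells expressing the fusion, while the design text has transduced cells in both arms. The 4 groups at 7 days were bone marrow control, bone marrow doxycycline, spleen control and spleen doxycycline, with 3 libraries each. A separate cohort was treated until signs of fatal disease, and 4 libraries of this secondary disease came from spleens of doxycycline-treated mice. No group had doxycycline without the shRNA, so an effect of the drug itself cannot be told apart from one of the knockdown. Total expected counts per library lay between 12.26 M (secondary disease replicate 4) and 39.42 M (spleen control replicate 3), M standing for mega-counts.

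Cbfb (ENSMUSG00000031885, chromosome 8, 105170674 to 105217989, plus strand, GRCm38), the gene of the RUNX-binding partner that forms the 5′ part of the fusion, measured 128 ± 9.93 CPM (SD, n = 3) in bone marrow control and 92.5 ± 3.85 in bone marrow doxycycline. In spleen it measured 133 ± 10.2 CPM in controls and 96.9 ± 36.9 with doxycycline, where the replicates stood at 117.5, 54.3 and 119 CPM. The 4 secondary disease libraries held 137, 133, 127 and 72.2 CPM. Neither difference passed the test: the log2 fold change was −0.47 ± 0.27 in bone marrow (adjusted p = 0.340) and −0.46 ± 0.27 in spleen (adjusted p = 0.547). With only the 6 bone marrow libraries in the model, the bone marrow difference passed (adjusted p = 0.00247, against 0.149 to 0.592 in the other settings run). Against spleen control, secondary disease had a log2 fold change of −0.18 ± 0.25 (adjusted p = 0.817). Myh11 (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372, minus strand) had 0 to 9 expected counts in each library and was not tested. Whether reads of the MYH11 part of the fusion were counted on mouse Myh11 is not given in the sources used here, and Cbfb counts also take in the normal allele, so these values do not measure the fusion itself.

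**Figure D1:**
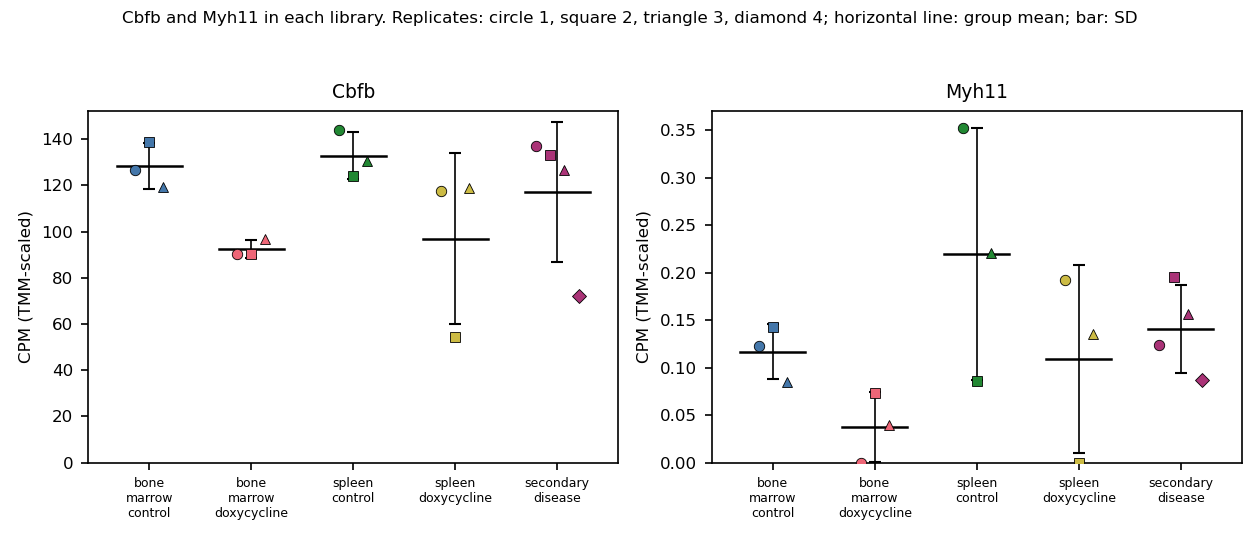
CPM (TMM-scaled) of Cbfb and Myh11 in each of the 16 libraries by group, with the group mean as a line and the SD as a bar. Spleen doxycycline replicate 2 lies at 54.3 CPM of Cbfb, and the other spleen doxycycline libraries at 117.5 and 119.

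The first comparison asked what 7 days of doxycycline changed in leukaemia cells of the bone marrow. Red cell genes rose: Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096, minus strand), an adult β-globin, went from 391 ± 250 CPM (SD, n = 3) in controls to 16780 ± 2104 (n = 3), a log2 fold change of 5.42 ± 1.00 (adjusted p = 0.0108). Alas2, the first enzyme of erythroid haem synthesis, rose from 26.6 ± 20.2 to 726 ± 94.3 CPM. Lmna (ENSMUSG00000028063, chromosome 3, 88480147 to 88509956, minus strand), encoding the nuclear lamins A and C, rose from 0.732 ± 0.596 to 104 ± 15.6 CPM (log2 fold change 7.17 ± 1.06, adjusted p = 0.00472), and the sphingosine kinase gene Sphk1 by 6.66 ± 1.09. In the other direction, the platelet receptor gene Gp1bb fell by 6.29 ± 1.18 (adjusted p = 0.0115), the growth factor gene Clec11a by 7.71 ± 1.68 (adjusted p = 0.0188) and the calpain gene Capn2 by 5.57 ± 1.12 (adjusted p = 0.0138). Among the other large changes, Pklr, Vgf, Atp7b, Hbb-bt and Rab3il1 rose, and Exosc6, Nos3, Fos, Ctla2a and Rgs1 fell.

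Of 27 erythroid genes, 18 rose, 0 fell and 9 did not pass, and 19 rose when adjusted over the list alone. The list's median log2 fold change was 2.27, with camera adjusted p = 1.25e-20 and adjusted p = 0.216 with an estimated correlation. The paralogous globin genes share reads, so the split between Hba-a1 (log2 fold change 3.22 ± 0.50) and Hba-a2 (4.32 ± 0.70), or between Hbb-bs and Hbb-bt, is uncertain. Haemoglobin genes took 0.212 to 0.416% of the counts in control libraries and 4.50 to 5.60% in doxycycline libraries. Of 11 megakaryocyte and platelet genes, 3 fell (Gp1bb, Treml1 and Rab27b), 0 rose and 8 did not pass, and 4 fell and 1 rose when adjusted over the list alone. The median was −0.89, with camera adjusted p = 0.00322 and adjusted p = 0.626 with an estimated correlation. Immediate early genes, switched on within minutes of a stimulus, fell in 7 of 22 cases and 15 did not pass, and 15 fell and 1 rose when adjusted over the list alone. Jun fell by 2.79 ± 0.53, Egr1 by 2.26 ± 0.41 and Fos by 5.39 ± 1.21. Their median was −1.73, with camera adjusted p = 2.65e-09 and adjusted p = 0.216 with an estimated correlation.

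Genes of the mitochondrial and integrated stress response rose in 9 of 31 cases and 22 did not pass, against 15 that rose and 1 that fell when adjusted over the list alone. Atf5, a transcription factor of this response, rose by 2.76 ± 0.38, the pseudokinase gene Trib3 by 3.35 ± 0.53 and Sesn2 by 1.99 ± 0.32 in log2 units. Camera gave adjusted p = 2.67e-08 for this list, and adjusted p = 0.216 with an estimated correlation. Among 26 targets of p53, Sesn2, Trp53inp1 and Mdm2 rose and 23 did not pass, and 10 rose when adjusted over the list alone (camera adjusted p = 0.000443, adjusted p = 0.216 with an estimated correlation). Interferon response genes went both ways: 4 of 44 rose, among them Isg15 (log2 fold change 2.95 ± 0.55) and Oasl2 (3.74 ± 0.91), Ifit2 fell by 1.30 ± 0.21 and 39 did not pass. Adjusted over the list alone, 9 rose and 3 fell, and camera gave adjusted p = 0.0155 for a rise (adjusted p = 0.766 with an estimated correlation). Of 24 cholesterol biosynthesis genes, 2 fell, Hmgcs1 among them, and 22 did not pass, with 8 falling when adjusted over the list alone (camera adjusted p = 0.000626, adjusted p = 0.319 with an estimated correlation). 

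Among 27 genes of the RUNX complex and haematopoietic transcription factors, Gata1, Gata2, Nfe2 and Lyl1 rose, Etv6 and Erg fell and 21 did not pass, while 5 rose and 5 fell when adjusted over the list alone. Gata2, a factor of stem, mast and early erythroid cells, went from 264 ± 28.9 to 679 ± 144 CPM (log2 fold change 1.36 ± 0.32, adjusted p = 0.0249). The receptor gene Tek fell from 123 ± 6.74 to 7.42 ± 0.371 CPM (log2 fold change −4.05 ± 0.95, adjusted p = 0.0250), in 3 of 3 libraries below every control. Receptor signalling genes Il4ra (2.94 ± 0.35) and Pim1 (2.80 ± 0.45) rose, as did the survival gene Bcl2l1 (1.34 ± 0.22). Runx1 (−0.67 ± 0.30, adjusted p = 0.208), Kit (1.01 ± 0.33, adjusted p = 0.0858), Il1rl1 (−0.81 ± 0.58, adjusted p = 0.479) and Mki67 (−0.03 ± 0.36, adjusted p = 0.974) did not pass. Without secondary disease replicate 4, which is in neither group, Kit passed with edgeR (adjusted p = 0.00667) and the others did not. Among lists of other cell types, all 22 mature neutrophil genes had a negative log2 fold change (median −1.16), but 0 passed with edgeR or DESeq2 and 1 with limma-voom (1 at an unadjusted p under 0.05), with camera adjusted p = 0.00208 and adjusted p = 0.733 with an estimated correlation. Of 22 B cell and plasma cell genes, Blnk rose, to 4.64 ± 1.57 from 0.461 ± 0.271 CPM, and the list median was 0.95 (camera adjusted p = 0.00504, adjusted p = 0.626 with an estimated correlation). The median log2 CPM of this list was 0.11, 0.31 and −0.58 in doxycycline replicates 1, 2 and 3. It was −1.84 to −0.48 in the controls, so replicate 3 lay within their range.

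In all, edgeR called 949 genes in this comparison, 572 higher and 377 lower with doxycycline, and 661 of them changed at least 2-fold; 11 of the 29 lists were called by camera. The count was 187, 23 and 232 without bone marrow control replicate 1, 2 or 3, and 191, 111 and 178 without doxycycline replicate 1, 2 or 3. Without secondary disease replicate 4, which belongs to neither group but enters the shared spread and the choice of genes tested (14263 without it, 14435 with it), 2428 genes were called, 948 of the 949 among them in the same direction.

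**Figure D2:**
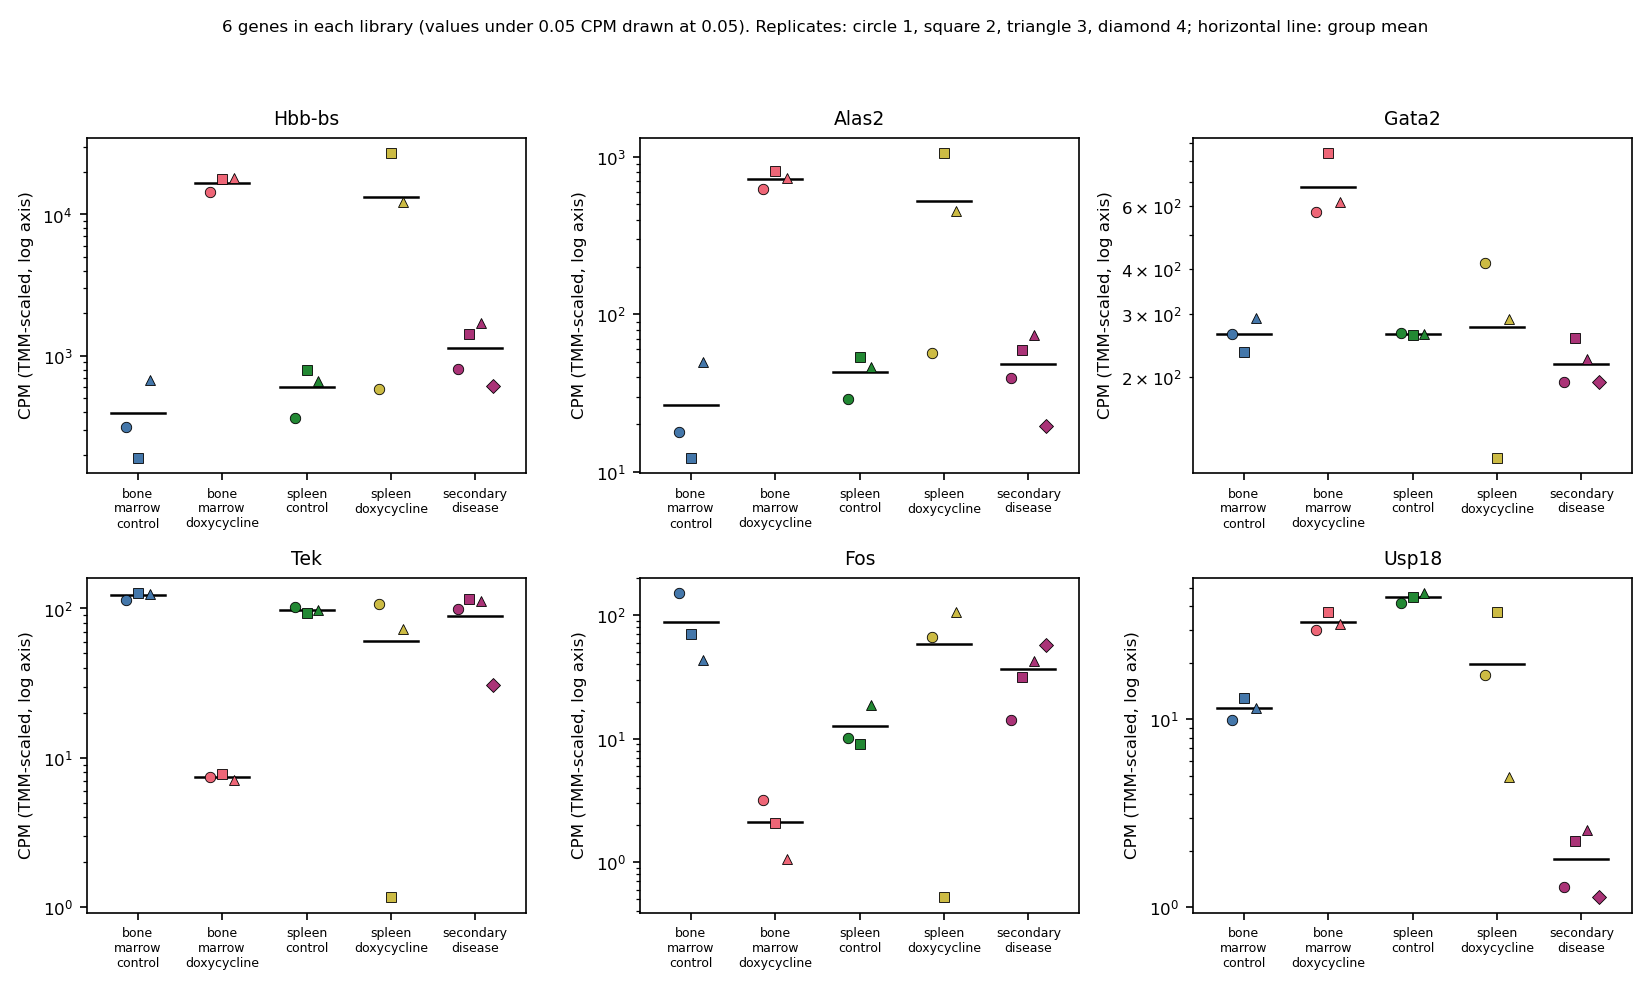
CPM (TMM-scaled, log axis) of 6 genes in each library by group, with the group mean as a line. Hbb-bs and Alas2 are high in the bone marrow doxycycline libraries and in spleen doxycycline replicates 2 and 3, while spleen doxycycline replicate 1 has 583 CPM of Hbb-bs, within the 361 to 789 CPM of the spleen controls.

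In spleen, the same treatment was compared with spleen control. Lmna rose from 2.64 ± 0.232 CPM (SD, n = 3) to 109 ± 114 (n = 3; log2 fold change 5.36 ± 0.94, adjusted p = 0.0365), Sphk1 by 5.61 ± 1.03 and the sialyltransferase gene St3gal2 by 7.07 ± 1.38 in log2 units. Without replicate 2 the log2 fold changes of these 3 genes were 4.16, 3.48 and 4.53. Each passed in 1 of the 6 fits that left out 1 library, the fit without replicate 1. Usp40 (ENSMUSG00000005501, chromosome 1, 87945119 to 88008551, minus strand), a ubiquitin peptidase gene, fell from 27.6 ± 2.80 to 11.8 ± 2.14 CPM (log2 fold change −1.23 ± 0.18, adjusted p = 0.0193), and F2r, the thrombin receptor gene, from 78.6 ± 2.38 CPM to 38.3, 12.2 and 12.6 CPM in replicates 1, 2 and 3. The phosphatase gene Dusp1 rose from 4.60 ± 0.531 to 26.6 ± 7.17 CPM (log2 fold change 2.53 ± 0.44, adjusted p = 0.0365). Fhdc1, Slc22a23, Acer3, Rhd and Hba-a2 rose as well, and Itpr1, Zfp185, Pdzd2, Fam3c, Socs1 and Ddx58 fell.

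Erythroid genes rose in 7 of 27 cases and 20 did not pass, while 21 rose when adjusted over the list alone. Hbb-bs rose by 4.46 ± 0.96 (adjusted p = 0.0491) and Hba-a2 by 3.52 ± 0.67 in log2 units. The list median was 2.19, with camera adjusted p = 1.02e-19 and adjusted p = 0.374 with an estimated correlation. The 3 libraries differed: Hbb-bs stood at 583, 27150 and 12217 CPM in replicates 1, 2 and 3 against 361 to 789 CPM in the controls. Among 44 interferon response genes, Ddx58, an RNA sensor gene, and Socs1 fell and 42 did not pass, while 2 fell when adjusted over the list alone. The list's median was −0.78, with camera adjusted p = 1.19e-12 and adjusted p = 0.374 with an estimated correlation. Its median log2 CPM was 4.08, 4.64 and 2.42 in replicates 1, 2 and 3 and between 5.10 and 5.21 in the controls. Hypoxia and glycolysis genes had a median of −0.43: Vegfa fell by 0.93 ± 0.17 and Hk2 by 0.99 ± 0.20, and 32 of 34 did not pass, with 3 rising and 4 falling when adjusted over the list alone (camera adjusted p = 8.59e-05, adjusted p = 0.374 with an estimated correlation). The median log2 CPM of this list was 6.56, 6.44 and 7.00 in replicates 1, 2 and 3 against 6.58 to 6.64 in the controls, so replicate 3 lay above them. All 41 cytosolic ribosomal protein genes and all 15 mitochondrially encoded genes had positive log2 fold changes (medians 0.25 and 0.58), yet 0 members passed with edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05. Camera gave adjusted p = 0.000182 and 0.00740 for these lists, and adjusted p = 0.734 for both with an estimated correlation. For mitochondrially encoded genes only replicate 3 lay above the controls (median log2 CPM 9.82, 10.10 and 11.41 against 9.86 to 10.32). For ribosomal protein genes replicates 1 and 3 did (10.72, 10.34 and 10.82 against 10.15 to 10.47). B cell and plasma cell genes had a median of 1.45 (camera adjusted p = 4.51e-05, adjusted p = 0.374 with an estimated correlation). Cd37 rose by 1.30 ± 0.28 and 21 of 22 did not pass, with 3 rising when adjusted over the list alone. The levels were low: the list's median log2 CPM was −1.76 to −1.67 in the controls and −1.44, −0.95 and 0.52 in replicates 1, 2 and 3, highest in replicate 3. Among other cell type lists, mature neutrophil genes had a median of −0.73 (camera adjusted p = 0.00179, adjusted p = 0.734 with an estimated correlation). Of its 22 members 0 passed with edgeR, DESeq2 or limma-voom and 1 had an unadjusted p under 0.05. Its median log2 CPM was −1.57, −0.02 and 0.63 in replicates 1, 2 and 3 and ran from 0.25 to 2.01 in the controls.

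Of the regulators, Gfi1b rose by 0.67 ± 0.14 (adjusted p = 0.0451). Runx1 (−0.71 ± 0.30, adjusted p = 0.348), Kit (1.00 ± 0.33, adjusted p = 0.189), Gata2 (0.06 ± 0.31, adjusted p = 0.974), Myc (−0.76 ± 0.24, adjusted p = 0.168) and Mki67 (0.27 ± 0.36, adjusted p = 0.851) did not pass. Of these genes, Kit alone passed with edgeR without secondary disease replicate 4 (adjusted p = 0.0189). In all, edgeR called 107 genes, 82 higher and 25 lower, 84 of them at 2-fold or more, and camera called 14 of 29 lists; limma-voom called 100 genes, 29 higher and 71 lower. The count was 1364, 37 and 13 without spleen doxycycline replicate 1, 2 or 3, and 2, 0 and 0 without spleen control replicate 1, 2 or 3, where 1318 and 1250 genes had an unadjusted p under 0.05 in the 2 fits with no call. With only these 6 libraries in the model edgeR called 1 gene, and without secondary disease replicate 4 it called 766, the 107 among them.

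The difference in the doxycycline effect between the tissues was tested as an interaction, spleen minus bone marrow. Dusp1, whose protein switches off MAP kinases, fell by 1.89 in bone marrow and rose by 2.53 in spleen in log2 units, a difference of 4.42 ± 0.61 (adjusted p = 0.0207). With doxycycline Dusp1 lay at 14.95 to 21.97 CPM in bone marrow and 20.49 to 34.46 in spleen. The controls of these tissues lay further apart, at 30.68 to 115.68 and 4 to 5.03 CPM. Pou4f1 (ENSMUSG00000048349, chromosome 14, 104461676 to 104467999, minus strand), a POU transcription factor gene, rose by 1.19 in bone marrow and fell by 0.88 in spleen (difference −2.06 ± 0.24, adjusted p = 0.00674). Xbp1, a transcription factor of the unfolded protein response, rose by 0.70 in bone marrow and fell by 0.84 in spleen (difference −1.54 ± 0.24, adjusted p = 0.0445). The other called genes were Phf11d (2.88 ± 0.40), Cenph (1.27 ± 0.20), Sumf1 (−1.08 ± 0.17) and Hspa12b (3.63 ± 0.58), the last with an average below the level set for naming and named here because only 7 genes were called. Phf11d lay at 2.33 to 2.6 CPM in the spleen controls and at 7.86 to 16.44 in the other 7-day libraries. Dusp1, Pou4f1, Xbp1 and Phf11d were also called between the controls of the tissues, with the opposite sign. The interaction uses those controls, so these calls are not independent of that difference. Beyond the 7 genes called, the nearest to passing among genes the rule named were Ppp1r15a (1.76 ± 0.32), Usp40 (−1.38 ± 0.26) and Nfkbiz (−1.71 ± 0.33), each with adjusted p = 0.0957. Without secondary disease replicate 4 these genes passed with edgeR (adjusted p = 0.0225, 0.0185 and 0.0185). No difference was called for Cbfb (0.02 ± 0.38, adjusted p = 1.00), Runx1 (−0.03 ± 0.43) or Gata2 (−1.30 ± 0.45, adjusted p = 0.410).

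Interferon response genes had a median difference of −1.32, with 0 of 44 members passing over all genes with edgeR and 10 lower when adjusted over the list alone; 8 passed with DESeq2, 2 with limma-voom and 20 at an unadjusted p under 0.05. Camera gave adjusted p = 3.77e-20, and adjusted p = 0.0823 with an estimated correlation. The list's median log2 CPM was 3.37 to 4.07 in bone marrow controls and 5.10 to 5.21 in spleen controls. With doxycycline it was 4.50 to 5.04 in bone marrow and 4.08, 4.64 and 2.42 in spleen replicates 1, 2 and 3. The controls thus differed with the opposite sign, and the interaction is not independent of that difference. Immediate early genes had a median difference of 1.76, where 1 of 22 passed (Dusp1) and 12 were higher when adjusted over the list alone, with camera adjusted p = 2.16e-12 and adjusted p = 0.0994 with an estimated correlation. The median log2 CPM of this list was 5.95, 3.09 and 4.72 in spleen doxycycline replicates 1, 2 and 3 against 4.50 to 4.81 in spleen controls, so only replicate 1 lay above them. The bone marrow controls had 6.90, 6.08 and 5.30 against 3.37 to 4.37 with doxycycline. For targets of p53 the median was −0.56, 0 of 26 passed with edgeR, 3 with DESeq2 and 1 with limma-voom (11 at an unadjusted p under 0.05), and 9 were lower and 1 higher when adjusted over the list alone. Camera gave adjusted p = 1.49e-07 for this list and adjusted p = 0.0692 with an estimated correlation. Its controls also differed with the opposite sign, at a median log2 CPM of 4.77 to 5.56 in bone marrow and 5.83 to 5.84 in spleen. Erythroid genes had a median of −0.24 and 0 of 27 passed with edgeR, 1 with DESeq2, 0 with limma-voom and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0340, adjusted p = 0.768 with an estimated correlation). The interaction called 7 genes, 4 higher and 3 lower, and camera 12 of 29 lists; DESeq2 called 250 genes and limma-voom 34. Leaving out a library gave 4, 1 and 3 (bone marrow control 1 to 3), 1, 1 and 1 (bone marrow doxycycline 1 to 3), 0, 0 and 1 (spleen control 1 to 3, with 853 and 838 genes at an unadjusted p under 0.05 in the fits with no call) and 37, 645 and 27 (spleen doxycycline 1 to 3), and 105 without secondary disease replicate 4.

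The 2 doxycycline effects called 50 genes in the same direction, 49 higher and 1 lower in both tissues, where independent lists of the same sizes would share 3.25 higher and 0.653 lower, and 3 genes in opposite directions. Across 14435 genes, which are not independent replicates, their log2 fold changes had a covariance of 0.471 and r = 0.475. No control library was shared. Without secondary disease replicate 4 the count was 364.

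Leukaemia cells of the 2 tissues were compared in the absence of doxycycline. In spleen control, Dusp1 was lower than in bone marrow control, at 4.60 ± 0.531 against 70.5 ± 42.8 CPM (SD, n = 3 each; log2 fold change −3.94 ± 0.47, adjusted p = 0.00771). Ppp1r15a, a stress-induced phosphatase subunit gene, had a log2 fold change of −1.69 ± 0.23. Dnaja4 (ENSMUSG00000032285, chromosome 9, 54698873 to 54716315, plus strand) and Hsph1, both chaperone genes of the heat shock families, were higher in spleen by 1.12 ± 0.14 and 0.85 ± 0.15. Xbp1 (1.08 ± 0.17), C1qtnf12 (1.51 ± 0.27), Pou4f1 (0.95 ± 0.17), Usp40 (1.10 ± 0.18) and F2r (1.97 ± 0.36) were higher too, and Phf11d, Wwc2, Clstn3, Mpzl1, Pkn3 and Nipsnap2 were lower.

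Granulocyte genes were lower in spleen. Of 15 primary granule genes, Prtn3 (10.8 ± 5.63 CPM in bone marrow, 0.773 ± 0.687 in spleen; log2 fold change −3.80 ± 0.67) and Prss57 fell and 13 did not pass, with 10 lower when adjusted over the list alone. Prss57 had 0 counts in the spleen controls and 1.23 ± 0.576 CPM in bone marrow. The list median was −3.45, with camera adjusted p = 3.22e-21 and adjusted p = 0.00567 with an estimated correlation. Mature neutrophil genes had a median of −3.29 and 22 of 22 negative values; 0 passed over all genes with edgeR, 14 with DESeq2, 19 with limma-voom and 21 at an unadjusted p under 0.05, and 21 were lower when adjusted over the list alone. Camera gave adjusted p = 5.82e-36, and adjusted p = 0.0219 with an estimated correlation. The most abundant of them, Ngp and S100a9, measured 292 ± 64.4 and 227 ± 58.5 CPM in bone marrow control and 30.9 ± 18.2 and 19.8 ± 8.91 in spleen control, and neither passed (adjusted p = 0.282 and 0.291). These are genes of normal neutrophils as well, and no normal neutrophil library was there to set them against. Adhesion and homing genes had a median of −0.36, with 0 of 31 passing over all genes with edgeR, 5 with DESeq2, 3 with limma-voom and 10 at an unadjusted p under 0.05, and 6 lower when adjusted over the list alone (camera adjusted p = 7.00e-06, adjusted p = 0.0471 with an estimated correlation). Targets of p53 had a median of 0.34, with 0 of 26 passing with edgeR, 6 with DESeq2, 5 with limma-voom and 11 at an unadjusted p under 0.05, and with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.07e-06, adjusted p = 0.0317 with an estimated correlation). Interferon response genes (median 0.78, camera adjusted p = 1.15e-13) and immediate early genes (median −1.11, camera adjusted p = 6.98e-10) were called too, each with adjusted p = 0.120 with an estimated correlation. Of their members 0 of 44 and 1 of 22 passed with edgeR, 8 and 4 with DESeq2, 3 and 2 with limma-voom and 18 and 11 at an unadjusted p under 0.05. The receptor gene Csf2rb measured 1693 ± 71.3 CPM in spleen and 450 ± 138 in bone marrow (adjusted p = 0.154), and Cxcr4 0.287 ± 0.219 and 3.75 ± 1.06 (adjusted p = 0.202).

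In all, 27 genes were called, 11 higher and 16 lower in spleen, and 17 of 29 lists; DESeq2 called 304 genes and limma-voom 170. The count was 12, 8 and 6 without bone marrow control replicate 1, 2 or 3, 7, 0 and 1 without spleen control replicate 1, 2 or 3 (681 genes at an unadjusted p under 0.05 in the fit with no call), 190 without secondary disease replicate 4 and 1927 with only these 6 libraries.

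After 7 days of doxycycline, 7 genes were lower in spleen than in bone marrow. Sumf1 (ENSMUSG00000030101, chromosome 6, 108107028 to 108185582, minus strand), whose product activates sulfatases, measured 27.0 ± 2.76 CPM (SD, n = 3) in spleen and 57.1 ± 2.99 (n = 3) in bone marrow (log2 fold change −1.08 ± 0.12, adjusted p = 0.00411). The growth factor receptor adaptor gene Grb10 (−1.77 ± 0.24), the phosphatase gene Ptpre (−1.19 ± 0.17), Pou4f1 (−1.12 ± 0.17), Prxl2a (−0.98 ± 0.15), Acbd3 (−0.76 ± 0.12) and Dym (−0.73 ± 0.11) made up the rest. Of the genes higher in spleen, 0 passed with edgeR, 223 passed with DESeq2 and 4 with limma-voom, and 878 had an unadjusted p under 0.05. Nearest were Eml4 (1.32 ± 0.23, adjusted p = 0.0556), Slc14a1, Fdps and Pacs1, which did not pass. Without secondary disease replicate 4, which is in neither group, these genes passed with edgeR (adjusted p = 0.00989, 0.00776, 0.00989 and 0.0267). In that fit 142 genes were called higher and 242 lower in spleen.

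Mature neutrophil genes had a median of −3.06 in this comparison, with 0 of 22 passing over all genes with edgeR, 11 with DESeq2, 7 with limma-voom and 20 at an unadjusted p under 0.05, and 20 lower when adjusted over the list alone. Camera gave adjusted p = 1.58e-24, and adjusted p = 0.119 with an estimated correlation. Cholesterol biosynthesis genes had a median of 0.39, with 0 of 24 passing with edgeR, 3 with DESeq2, 1 with limma-voom and 13 at an unadjusted p under 0.05, and 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 4.39e-07, adjusted p = 0.119 with an estimated correlation). Targets of MYC and of ribosome biogenesis had positive values in 39 of 40 cases (median 0.25, camera adjusted p = 1.06e-06, adjusted p = 0.251 with an estimated correlation); 0 passed with edgeR, DESeq2 or limma-voom and 9 had an unadjusted p under 0.05. Tek measured 106, 1.16 and 73.4 CPM in spleen doxycycline replicates 1, 2 and 3 and 7.42 ± 0.371 in bone marrow doxycycline (log2 fold change 3.02 ± 0.91, adjusted p = 0.214). With DESeq2 size factors 4 genes were higher and 14 lower. The count of 7 became 1, 1 and 1 without bone marrow doxycycline replicate 1, 2 or 3, 22, 1072 and 39 without spleen doxycycline replicate 1, 2 or 3, 384 without secondary disease replicate 4, and 0 with only these 6 libraries (1067 at an unadjusted p under 0.05).

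**Figure D3:**
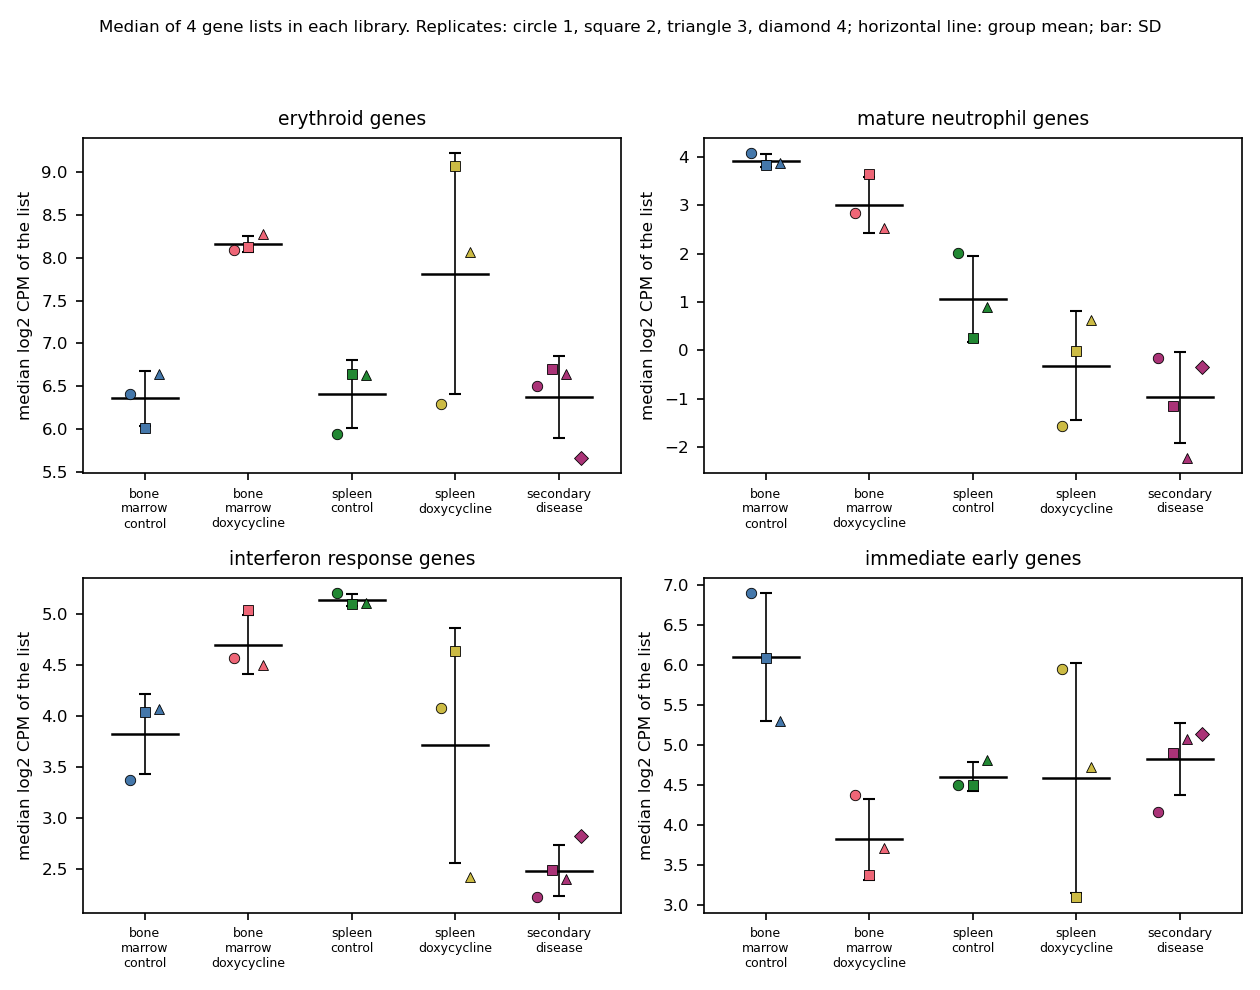
Median log2 CPM of 4 gene lists in each library by group, with the group mean as a line and the SD as a bar. The interferon response list lies between 5.10 and 5.21 in the spleen controls and between 2.22 and 2.82 in the secondary disease libraries, and the erythroid list at 6.30, 9.07 and 8.07 in spleen doxycycline replicates 1, 2 and 3.

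Secondary disease was compared with spleen control to ask how leukaemia that had become fatal under doxycycline differed from untreated leukaemia of the spleen. Its libraries came from another cohort at a later time, so cohort, time and treatment cannot be told apart. Interferon-induced genes were far lower: Usp18 (ENSMUSG00000030107, chromosome 6, 121245906 to 121270917, plus strand), a brake on interferon signalling, measured 1.81 ± 0.716 CPM (SD, n = 4) against 44.6 ± 2.66 (n = 3), a log2 fold change of −4.59 ± 0.50 (adjusted p = 0.000607). Tgtp2, an interferon-inducible GTPase gene whose closely similar copies leave its own share of reads uncertain, fell by 5.83 ± 0.64, Rtp4 by 6.95 ± 0.90 and Oas2 by 7.01 ± 0.89 in log2 units. Tph1, the tryptophan hydroxylase gene, fell from 1179 ± 29.0 to 26.6 ± 5.11 CPM (adjusted p = 0.0131), the thrombin receptor gene F2r from 78.6 ± 2.38 to 10.7 ± 1.18 CPM and Ptgir, C2cd4a, Nav2 and Ankrd33b fell as well.

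Of 44 interferon response genes, 21 fell, 0 rose and 23 did not pass, with 32 falling when adjusted over the list alone. The median was −1.79, with camera adjusted p = 4.10e-56 and adjusted p = 0.00844 with an estimated correlation, the only list of the 29 that stayed called. Ddx58 fell by 3.13 ± 0.35, Irgm1 by 2.56 ± 0.33 and Bst2 by 3.04 ± 0.45. The spleen controls held the highest median log2 CPM of this list, 5.10 to 5.21. Bone marrow controls had 3.37 to 4.07 and secondary disease 2.22 to 2.82, so these falls are measured from a high control level. In spleen against bone marrow control, the log2 fold change was 1.96 in Usp18 (adjusted p = 0.156) and 1.97 in F2r (adjusted p = 0.0438). Among 26 targets of p53, Cdkn1a, which arrests the cell cycle, fell from 229 ± 13.7 to 68.1 ± 21.9 CPM (log2 fold change −1.75 ± 0.34, adjusted p = 0.0176), Eda2r and Tnfrsf10b fell and 23 did not pass. Adjusted over the list alone, 9 fell and 2 rose (camera adjusted p = 2.21e-05, adjusted p = 0.119 with an estimated correlation). Cdkn1a also had a log2 fold change of 1.49 in spleen against bone marrow control, which did not pass (adjusted p = 0.147). Of 22 mature neutrophil genes, Chil3 fell and 21 did not pass, with 9 falling when adjusted over the list alone (median −1.84, camera adjusted p = 2.86e-10, adjusted p = 0.490 with an estimated correlation). All 15 mitochondrially encoded genes had positive values (median 1.13); 0 passed over all genes with edgeR or limma-voom, 4 with DESeq2 and 13 at an unadjusted p under 0.05, and 13 rose when adjusted over the list alone (camera adjusted p = 1.09e-09, adjusted p = 0.497 with an estimated correlation). Mitochondrial transcripts took 7.78% of the counts in secondary disease replicate 4, 3.16 to 5.30% in replicates 1 to 3 and 2.20 to 2.86% in the spleen controls. The cytokine and JAK-STAT feedback list held Socs1, Cish and Spred1, which fell, and 32 of 35 that did not pass. For this list the median was −0.09 and the mean 0.07, while camera called a fall (adjusted p = 0.0220, adjusted p = 0.490 with an estimated correlation).

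Several of the genes that rose are expressed in nerve tissue, and secondary disease replicate 4 stood apart in them. Map1b (ENSMUSG00000052727, chromosome 13, 99421446 to 99516540, minus strand), a microtubule protein gene of neurons, measured 114, 86.1, 87.7 and 346 CPM in replicates 1 to 4 against 8.84 ± 1.03 in controls (log2 fold change 4.16 ± 0.60, adjusted p = 0.00297). The clusterin gene Clu measured 44.5, 29.7, 28.7 and 249 CPM against 1.17 ± 0.227, and the synaptic gene Cplx2 11.6, 7.23, 6.29 and 296 against 0.145 ± 0.134. Olfm1 and Tppp had the same pattern. Stard8 (4.16 ± 0.62), Acer3 (4.41 ± 0.67) and the protease gene Pcsk5 (4.88 ± 0.95) rose too, with 29.4, 40.6, 41.7 and 14.9 CPM of Stard8 in replicates 1 to 4. Without replicate 4, Map1b (adjusted p = 0.00161), Clu (adjusted p = 0.00356) and Cplx2 (adjusted p = 0.00380) still passed. Cbfb, Runx1 (−0.63 ± 0.28, adjusted p = 0.301), Gata2 (−0.28 ± 0.29, adjusted p = 0.750), Il1rl1 (−0.50 ± 0.54, adjusted p = 0.757) and Mki67 (−0.30 ± 0.34, adjusted p = 0.771) did not pass, nor did 27 of 27 erythroid genes (0 with edgeR or limma-voom, 1 with DESeq2, 6 at an unadjusted p under 0.05).

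In all, 293 genes were called, 108 higher and 185 lower, 256 at 2-fold or more, and 9 of 29 lists. The count was 88, 61 and 75 without spleen control replicate 1, 2 or 3, 173, 147 and 154 without secondary disease replicate 1, 2 or 3, and 523 without replicate 4, 282 of the 293 among them in the same direction. Between this comparison and that of spleen doxycycline with the same controls, 34 genes changed in the same direction, 21 higher and 13 lower, and 0 in opposite directions. Independent lists would share 0.614 higher and 0.32 lower. Unchanged groups simulated with shared controls shared 0, but few genes could be called there. That 0 therefore does not measure what shared controls add to an overlap of called genes. The covariance of the log2 fold changes was 0.57, against 0.17 in simulation, and r was 0.477, against 0.534 in simulation. The observed r was thus not above the simulated one. With 3 controls no split into separate control sets of 2 exists, so how many of the 34 genes were owed to the shared controls was not measured. Without replicate 4 the count was 141.

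Set against spleen doxycycline at 7 days, secondary disease had 9 of 44 interferon genes and 8 of 27 erythroid genes lower with edgeR. With limma-voom 2 and 1 passed in either direction. Both list calls were lost with an estimated correlation (adjusted p = 0.223 and 0.283). Slc6a20a (ENSMUSG00000036814, chromosome 9, 123634770 to 123678885, minus strand), an amino acid transporter gene, measured 1.03 ± 0.620 CPM (SD, n = 4) against 18.4 ± 12.1 (n = 3; log2 fold change −4.13 ± 0.49, adjusted p = 0.0114). Usp18 fell by 3.42 ± 0.48, Oas2 by 5.36 ± 0.86, Lgals3bp by 3.81 ± 0.63 and Rtp4 by 4.99 ± 0.85. Pkn3, a kinase gene, rose from 27.6 ± 10.8 to 79.3 ± 6.28 CPM (log2 fold change 1.52 ± 0.23, adjusted p = 0.0201), and Il6st, the shared receptor subunit of the interleukin-6 family, by 1.84 ± 0.30. Kcnq5, Map1b, Inpp5a, Wwc2, Prkch and Clu rose, and Rhd, Oas3 and Atp2b4 fell. Of these, Map1b and Clu are among the genes in which secondary disease replicate 4 stood apart.

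Of 44 interferon response genes, 9 fell and 35 did not pass, with 23 falling and 1 rising when adjusted over the list alone (median −1.11, camera adjusted p = 1.35e-17, adjusted p = 0.223 with an estimated correlation). The spleen doxycycline libraries were spread in these genes: Usp18 stood at 17.3, 37.1 and 4.94 CPM in replicates 1, 2 and 3. Erythroid genes fell in 8 of 27 cases and 19 did not pass, with 23 falling when adjusted over the list alone (median −2.28, camera adjusted p = 3.29e-20, adjusted p = 0.283 with an estimated correlation). Hba-a2 measured 1780 ± 556 CPM in secondary disease and 1953, 28619 and 14567 in spleen doxycycline replicates 1, 2 and 3. Cholesterol biosynthesis genes had positive values in 23 of 24 cases (median 0.31); 0 passed over all genes with edgeR or limma-voom, 4 with DESeq2 and 7 at an unadjusted p under 0.05, and 4 were higher when adjusted over the list alone (camera adjusted p = 3.60e-06, adjusted p = 0.223 with an estimated correlation). Cell cycle genes had negative values in 44 of 46 cases (median −0.30); 0 passed with edgeR or limma-voom, 3 with DESeq2 and 6 at an unadjusted p under 0.05, and camera gave adjusted p = 1.55e-05 and adjusted p = 0.767 with an estimated correlation. In this list 2 libraries stood apart, spleen doxycycline replicate 2 at a median log2 CPM of 7.65 and secondary disease replicate 4 at 6.24. The other 5 lay between 6.85 and 6.97.

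In all, 134 genes were called, 32 higher and 102 lower, 104 at 2-fold or more, and 11 of 29 lists, while limma-voom called 32 higher and 33 lower. The count was 7, 0, 0 and 711 without secondary disease replicate 1, 2, 3 or 4 (2542 and 2503 at an unadjusted p under 0.05 in the 2 fits with no call), 1336, 35 and 440 without spleen doxycycline replicate 1, 2 or 3, and 0 with only these 7 libraries (717 at an unadjusted p under 0.05).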

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

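The splits of the samples and the depth test were planned, and the other tests of explanations were chosen after their results were seen.

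Secondary disease replicate 4 lay far from replicates 1 to 3 in 9 of the 11 values that stood apart among the 50 checked in this group, where chance sets apart about 1 group in 20. Its total was 12.26 M expected counts, and its r with the other libraries was 0.777 to 0.835, while the other 15 libraries had r of at least 0.904 with one another. Lower depth is argued against, because replicates 1 to 3 thinned to its total kept r of at least 0.984. The secondary disease itself is argued against as the source of the brain markers: the highest brain marker median of replicates 1 to 3 was −0.68 (log2 of CPM + 0.5), within the range of −0.93 to −0.07 of the 7-day libraries, and that of replicate 4 was 6.86. RNA of brain tissue may have entered this library: of 25 markers, 23 exceeded every other library, the lowest of 4 median ratios was 31.77 (microglia), Snap25 had 457 CPM and Mbp 953 CPM, and the GFP sort should have removed such cells, while Gfap was higher in another library.

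In replicate 4, list medians in log2 CPM stood apart for the RUNX complex and haematopoietic transcription factors (6.04), megakaryocyte and platelet genes (4.87), cell cycle genes (6.24) and cholesterol biosynthesis genes (5.2), each below replicates 1 to 3. Cbfb (72.16 CPM), Runx1 (99.4 CPM) and Runx2 (21.34 CPM) were lower there, and Cebpa (4.163 CPM) was higher. The median of NF-kB and inflammatory genes stood apart in replicate 2, at 3.09. Elane stood apart in replicate 1, at 0.2484 CPM beside 0 counts in the other 3 libraries.

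In bone marrow with doxycycline, 18 of 27 erythroid genes rose and 3 of 11 megakaryocyte genes fell with edgeR. Members that passed in either direction were 15 and 0 with limma-voom, 19 and 5 with DESeq2, and 20 and 6 at an unadjusted p under 0.05. Both list calls were lost with an estimated correlation (adjusted p = 0.216 and 0.626). For the rise, erythroid cells of the recipient in the sorted sample cannot be told apart from differentiation of the leukaemia cells, which was not tested: in the 5 libraries with raised haemoglobin, the rise of other erythroid genes over that of haemoglobin genes was 0.129 to 0.247, with a highest over lowest of 1.912, but both would give such a ratio, and 14 of its 23 genes had been called as rising. For the falls, dilution by such cells would lower the genes of the leukaemia cells alike. The median of genes linked to the leukaemia (−0.137) lay 2.504 ± 0.706 above the smallest of the 3 falls that passed, −2.64 in Rab27b. These 3 genes were picked by their falls in the same fit, which puts them below a median near 0, so this gap does not decide. For the list as a whole, dilution cannot be told apart either. Megakaryocyte genes minus genes linked to the leukaemia gave a difference of medians of −0.749 with a bootstrap SE of 0.656, too wide to decide. A first form of the test, the megakaryocyte median alone (−0.886), did not decide either. Whether the shRNA lowered the fusion transcript stays open too, since Cbfb had a log2 fold change of −0.471, its counts hold the normal allele, and it passed only in the model of the 6 bone marrow libraries (adjusted p = 0.00247; 0.149 to 0.592 in the other settings run).

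The 3 spleen doxycycline libraries differed from one another: on a scale from bone marrow control (0) to bone marrow doxycycline (1), replicates 1, 2 and 3 lay at 0.06, 1.06 and 0.48. A swap between replicate 1 and a spleen control is argued against, because the highest spleen control lay at 0.12. No response in replicate 1, or an animal that was not treated, cannot be told apart from a weak response: over genes that changed 2-fold in both replicates 2 and 3, its mean place was 0.127 on a scale from spleen controls (0) to these 2 libraries (1), under the 95% prediction limit of 0.181 for a control left out. Replicate 1 did stand away from the spleen controls elsewhere: on a like scale to secondary disease its mean place was 0.263, above a limit of 0.114, its interferon median was 4.08 log2 CPM against 5.10 to 5.21, and Phf11d, Dusp1, Pou4f1 and Xbp1, called with it among the libraries, lay outside the control range. Bone marrow controls also lay at 0.31 or above on that second scale without doxycycline, so a shift along it does not decide.

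Between spleen and bone marrow, the doxycycline effect differed by an interaction test for 7 genes: Xbp1 (−1.537), Dusp1 (4.418), Sumf1 (−1.081), Cenph (1.265), Pou4f1 (−2.064), Phf11d (2.877) and Hspa12b (3.628), in log2 units as spleen minus bone marrow. By camera, 12 lists differed in the same sense, with median log2 differences of 0.76 for primary granule genes, −0.24 for erythroid, 0.364 for cell cycle, −0.562 for p53 target, −1.315 for interferon response and 1.763 for immediate early genes. The others were 0.337 for cytosolic ribosomal protein genes, 0.752 for mitochondrially encoded, 0.265 for nuclear-encoded oxidative phosphorylation, −0.244 for integrated stress response, −0.229 for hypoxia and −0.178 for cytokine feedback genes. With an estimated correlation between genes 0 of the 12 passed, the lowest adjusted p being 0.0692 for p53 target genes. With that correlation 4 lists had an unadjusted p under 0.05, and fry called 3 lists. Of the 7 genes, Dusp1, Pou4f1, Xbp1 and Phf11d also differed between the controls of the tissues, with the opposite sign. Among the lists, interferon response, p53 target, immediate early and primary granule genes also had medians of the opposite sign between those controls.

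Other splits of the same samples were counted for each comparison. For secondary disease against spleen control, 1 of 35 splits, the real one, gave as many as 293 genes and the highest other gave 102. That share is under 0.05, but it is the smallest that 35 splits can give, and it was not adjusted over the 7 comparisons. Chance is thus argued against but not excluded. For secondary disease against spleen doxycycline, 5 of 35 splits gave at least 134 and the highest other gave 2008, so chance is not excluded; the 4 other splits all part secondary disease replicate 4 from replicates 1 to 3, a structure of the samples. For the interaction, 5 of 100 drawn splits gave at least 7 and the highest other gave 1612, so chance is not excluded; 3 of these called 1459 to 1612 genes with spleen doxycycline replicates 2 and 3 kept together, again a structure of the samples. The comparisons of 3 against 3 have 10 splits, too few splits for a share under 0.05. In each of them 1 split, the real one, gave the real count: 949 for bone marrow doxycycline, 107 for spleen doxycycline, 27 for the controls of both tissues and 7 for doxycycline in both tissues, with 0 as the highest other with edgeR.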

How the results depend on the processing

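The alternatives were planned, except leaving out secondary disease replicate 4 from comparisons that do not use it, which was chosen after the data were seen. Counts are given in the order bone marrow doxycycline, spleen doxycycline, interaction, tissues in controls, tissues with doxycycline, secondary disease against spleen control and against spleen doxycycline; with edgeR as reported they were 949, 107, 7, 27, 7, 293 and 134.

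With no filter on low counts they were 349, 10, 2, 7, 2, 134 and 26; this setting tests more genes. With the replicate number as a block they were 1966, 374, 39, 117, 85, 421 and 347, where secondary disease replicate 4 is alone in its block level. Of 30 pairs of libraries checked, 6 had a closest partner of the same number. Whether libraries of the same number came from the same mouse is not given, and this check cannot tell. If bone marrow and spleen shared mice, the main model leaves that pairing out. With only the groups compared they were 4929, 1, 23, 1927, 0, 404 and 0 (1067 and 717 genes at an unadjusted p under 0.05 beside the 0 counts of edgeR; DESeq2 called 438 and 866 and limma-voom 63 and 65 there with all libraries). The DESeq2 Wald test called 1996, 715, 250, 304, 438, 756 and 866, limma-voom 925, 100, 34, 170, 63, 348 and 65, and the test against a 1.2-fold change 530, 24, 3, 13, 2, 215 and 52. DESeq2 size factors gave 18 and a mean count of at least 50 gave 26 for tissues with doxycycline, and stayed within 1.5 times elsewhere. The cause was not tested for these, beyond what a setting itself changes.

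Leaving out 1 library of the groups compared gave 23 to 232, 0 to 1364, 0 to 645, 0 to 12, 1 to 1072, 61 to 523 and 0 to 1336 genes, with the unadjusted counts beside each 0 in the report. Without secondary disease replicate 4 the counts were 2428, 766, 105, 190, 384, 523 and 711, and the biological coefficient of variation was 0.27, against 0.421 with it. Of the genes reported, 948, 107, 7, 27, 7, 282 and 133 were called there in the same direction.

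Lists called by camera were 11, 14, 12, 17, 16, 9 and 11. With an estimated correlation they were 0, 0, 0, 4, 0, 1 and 0 (unadjusted p under 0.05: 4, 3, 4, 10, 4, 2 and 4), and by fry 6, 0, 3, 4, 3, 2 and 1 (unadjusted: 9, 7, 4, 10, 8, 8 and 5). Secondary disease against spleen doxycycline had 7 to 11 lists when 1 library was left out, 7 without secondary disease replicate 3. The overlap of both doxycycline effects was 50 genes, 181 with the block and 364 without secondary disease replicate 4, and that of spleen doxycycline with secondary disease 34, 82 and 141.

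In the 3 comparisons with a control of the same tissue, Cbfb kept a negative log2 fold change in the settings run; its sign changed in others. In bone marrow it passed with only the groups compared (−0.46, adjusted p = 0.00247, against 0.149 to 0.592 in the other settings run), and in spleen and secondary disease it passed in 0 settings with edgeR, DESeq2 or limma-voom. Leave-one-out values were −0.545 to −0.433 in bone marrow, −0.63 to −0.169 in spleen and −0.259 to −0.008 in secondary disease. Among genes named, 1 value was reversed: Spi1 in secondary disease against spleen doxycycline was 1.04 without spleen doxycycline replicate 1 (adjusted p = 0.0212) and −0.129 with it (adjusted p = 0.917); leaving out other libraries gave −0.565 to −0.088, and the cause was not tested. A change of sign in a gene that passed under neither setting was not counted as reversed. Depth limits genes with few counts, above all in secondary disease replicate 4 at 12.26 M expected counts.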

Other observations

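The genes here and the test of spleen doxycycline replicate 3 were chosen after their values were seen.

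Erg, an ETS factor gene of stem cells and megakaryocytes, fell in bone marrow with doxycycline from 78.3 ± 7.53 CPM (SD, n = 3) to 7.84 ± 1.88 (n = 3), a log2 fold change of −3.32 ± 0.87 (adjusted p = 0.0378, edgeR). Fli1, a related factor gene, measured 130 ± 7.84 and 33.1 ± 1.64 CPM and did not pass (−1.98 ± 0.60, adjusted p = 0.0636). In spleen with doxycycline Erg ran from 1.36 to 72.4 CPM, against 54.6 ± 0.796 in spleen control.

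Xist, transcribed from the inactive X chromosome, averaged 1729 ± 38.5 CPM in spleen control, 623 ± 561 in spleen doxycycline and 38.0 ± 56.5 in secondary disease (SD, n = 3, 3 and 4). In bone marrow it averaged 1039 ± 226 CPM in controls and 435 ± 280 with doxycycline. Secondary disease against spleen control had a log2 fold change of −5.51 ± 1.34 in Xist (adjusted p = 0.0518), which did not pass. The median log2 fold change of 428 X-linked genes in that comparison was 0.003, and that of autosomal genes 0.016.

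A leukaemia clone shared with the secondary disease libraries may explain why spleen doxycycline replicate 3 resembled them. No clone is given for any library in the sources used here. A shared cohort would go against the design text, which has secondary disease in a separate cohort. On a scale from spleen control (0) to secondary disease replicates 1 to 3 (1), spleen doxycycline replicates 1 and 2 lay at 0.33 and 0.42. Replicate 3 of spleen doxycycline lay at 0.75. Its closest library was secondary disease replicate 2 (r = 0.97 across genes, which are not independent replicates), against 0.942 within its own group. Bone marrow libraries lay at 0.43 to 0.60 on the same scale. Whether these share a clone with secondary disease is not given either, so a place along this scale does not decide.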
